A study of Hermetia illucens with 45 samples.

How the data were processed

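The measurement was bulk RNA sequencing of whole larvae of the black soldier fly, Hermetia illucens. Per the labels, larvae 5 days old were left untreated, injected with phosphate-buffered saline (PBS) or injected with 5000 cells of the Gram-negative bacterium Pseudomonas protegens Pf-5, and were collected 2, 6 and 13 h later. Each library came from 2 pooled larvae, and each of the 9 groups held 5 libraries, 45 in all, with paired 150 bp reads. Rearing was at 27 °C and 65% humidity with 16 h of light and 8 h of dark. The labels describe the replicates as separate pools of larvae.

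The deposited values were raw counts per gene, whole numbers with 1 column per library, made by the authors. STAR is named per the submitters' processing notes, without a version. Its role, the counting tool, its treatment of strand and of reads with several matches, the genome build and the annotation were not given in the sources used here. Columns were assigned to libraries through the library codes in the labels. The table held 15196 rows, and 15187 of them matched a gene symbol of the RefSeq annotation of assembly iHerIll2.2.curated. The other 9 rows were headed by single numbers or fragments of words, named no gene, took 0.0204% to 0.0516% of a library's counts, and were kept out of library sizes and of the tests of genes. Since the authors' build was not given, the annotation was used only for symbols, gene classes and the order of neighbouring genes, and no coordinates are printed. It paired nearly all rows with numbered identifiers only, without product names.

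Library depth was 7.21 to 21.4 M counts (M, mega), with a median of 14.1 M, and 10194 to 11944 genes had at least 1 count. Genes were filtered with filterByExpr, which left 10485, and scaled with TMM (trimmed mean of M-values). Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with robust dispersion and robust quasi-likelihood fits, 1 factor of 9 groups over all 45 libraries, and 36 residual degrees of freedom. Wounding was PBS-injected against untreated larvae, and infection was bacteria-injected against PBS-injected larvae, at each of the 3 times, as the series design states. Further tests compared untreated larvae at 6 h and 13 h with 2 h, and asked whether the wounding or infection effect differed between times. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the size of the change divided by the square root of F. Levels are in CPM, counts per M counts of the TMM-scaled library size, given as mean ± SD with n = 5 libraries.

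The choices of groups, tests, alternatives, gene lists and the rule for named genes were made before the data were examined. The 31 gene lists (immune effectors, signalling, stress, metabolism and others) were written as patterns for product names. They matched 0 rows, since names were lacking, so no list was tested. The rule for named genes took, for each comparison, the genes with the largest fold change among those called, with a mean of at least 5 CPM in the higher group, no overlap between the 5 + 5 libraries, and with a product name. Where identifiers cannot be joined to names it allows at most 2 identifiers in each direction per comparison, and these were taken without the condition on names. All 5 libraries of 1 group thus lay on 1 side of all 5 of the other for each gene it took. Groups described in their place were chosen after the row names or values had been seen: the mitochondrially encoded genes, gene classes, runs of neighbouring genes, genes called at 2 h and followed in other libraries, and the most abundant gene. A run was at least 3 tested genes in a row along the annotation, all called in 1 direction with a log2 fold change of at least 1, and its number was compared with 1000 permutations of the calls over the gene order. Sets of genes were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. A fold against a group with 0 counts was computed against a floor of 3 counts over the group's libraries, and a fold against 1 to 3 counts is given with its 95% Poisson interval, both of which cover counting error only.

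Replicate pairs within groups were compared: over 90 pairs the chi-square per degree of freedom was at least 9.02, so no pair agreed within sampling noise. The biological coefficient of variation of a pair ranged from 0.0904 to 0.554, with a median of 0.323. The pipeline was tested on simulated counts for the tested genes, with 200 genes changed. Genes changed 4-fold were recovered in 86.4% of cases for infection at 2 h and in 92.4% for wounding at 2 h, those changed 2-fold in 47.8% and 35.8%, and those changed 1.5-fold in 13.4% and 11.9%. The alternatives were DESeq2-type size factors, DESeq2 1.42.0 (Wald test, and a likelihood-ratio test for differences between times), limma-voom with sample weights, no filter and a stricter one (1 CPM in 15 libraries), fits on the 10 libraries compared or the 15 of the same time, the replicate number as a block, stricter thresholds, and each library left out. Alternatives added after seeing the data left out 3 libraries at 6 h, the TMM factor, or the most abundant gene.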

Results

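The series asked how black soldier fly larvae respond to a sterile wound and to a Gram-negative infection over the hours after injection. Gene counts were measured in 45 libraries of 2 pooled whole larvae each: untreated, PBS-injected and bacteria-injected larvae at 2, 6 and 13 h, with 5 libraries per group. Total counts ranged from 7.21 to 21.4 M per library. Mean ± SD was 15.2 ± 1.26, 10.6 ± 2.33 and 14.4 ± 1.79 M in untreated larvae at 2, 6 and 13 h. It was 14.7 ± 3.95, 9.93 ± 4.10 and 17.1 ± 3.17 M in PBS-injected larvae, and 14.2 ± 3.02, 14.4 ± 3.32 and 13.6 ± 3.85 M in bacteria-injected larvae. The first principal component held 54.9% of the variance and set the 13 h libraries apart from the others. The second held 15.6% and was highest in bacteria-injected larvae at 6 h (65.1 ± 10.6) and 13 h (90.6 ± 11.0).

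Wounding at 2 h, the response to the injection itself, was read from PBS-injected against untreated larvae. It raised a set of genes from near the detection floor to high levels and lowered a smaller set. LOC119656618 stood at 1426 ± 429 CPM after PBS injection and 0.0697 ± 0.0762 CPM in untreated larvae, a log2 fold change of 14.15 (SE 0.92, edgeR adjusted p = 4.4e-15). Without untreated replicate 4, which held 3 of its 6 untreated counts, the ratio of 20469 became 32843, with a counting interval of 11238 to 159259. LOC119656623 stood at 485.5 ± 155 CPM, against 2 counts over all untreated libraries, a ratio of 20913 with a counting interval of 5789 to 172683 (edgeR adjusted p = 1.2e-14), or 33386 (5992 to 1318680) without untreated replicate 2 and 33554.5 (6022 to 1325330) without untreated replicate 4. Both belonged to a run of 19 neighbouring genes that were all higher, by log2 fold changes of 6.10 to 14.15. Summed over the run, these genes rose from 5.35 ± 2.61 CPM in untreated larvae to 6683 ± 2630 CPM after PBS injection. Among the genes that fell, LOC119647044 went from 76.4 ± 27.3 to 7.71 ± 4.68 CPM (log2 fold change -3.32, SE 0.60, edgeR adjusted p = 1.6e-04). LOC119650981 went from 16.2 ± 4.02 to 1.70 ± 0.548 CPM (log2 fold change -3.26, SE 0.35, edgeR adjusted p = 3.4e-09).

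In all, 281 genes were higher and 90 lower after wounding at 2 h among the 10485 tested, 214 and 64 of them by at least 2-fold. Of the 278 genes changed at least 2-fold, 49 lay in 6 runs of neighbours. Over 1000 permutations the mean was 0.083 runs (permutation p = 0.000999, the smallest they can give). How the authors' counting treated reads with several matches was not given in the sources used here, and whether these neighbours are near-identical copies was not tested. Values of single members of a run are therefore less certain than the sum over the run.

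**Figure D1:**
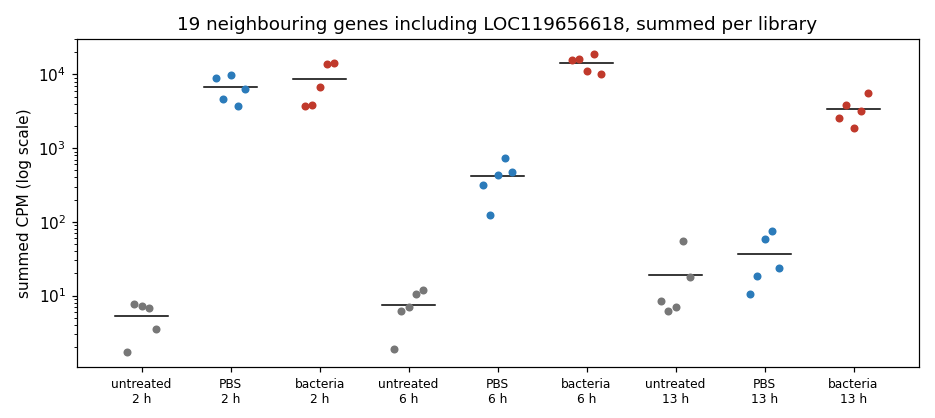
Summed CPM (log scale) of the 19 neighbouring genes that include LOC119656618, with 1 point per library, coloured by treatment, and a line at each group mean. Untreated larvae stayed at 5.35 to 19.1 CPM on average, PBS-injected larvae went from 6683 CPM at 2 h to 37.1 CPM at 13 h, and bacteria-injected larvae averaged 3402 CPM or more at each time, with single libraries down to 1871 CPM at 13 h.

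Wounding at 6 h still raised part of the genes raised at 2 h. LOC119654856 stood at 222.5 ± 73.7 CPM after PBS injection and 0.271 ± 0.306 CPM in untreated larvae (log2 fold change 9.55, SE 0.66, edgeR adjusted p = 4.1e-14, and 10.18 without untreated replicate 3). LOC119647898 stood at 326 ± 114 against 0.758 ± 0.660 CPM (log2 fold change 8.96, SE 0.71, edgeR adjusted p = 3.0e-12). Of the 281 genes higher at 2 h, 103 were higher and 2 lower at 6 h (63 higher with only the 10 libraries compared), with a median log2 fold change of 0.66 over the 281 (camera p = 3.5e-07 with an estimated correlation). In the run of 19 genes, 15 were still higher, and its sum was 417 ± 226 CPM against 7.47 ± 3.90 CPM in untreated larvae. LOC119655162 was lower, at 38.0 ± 25.2 against 191 ± 54.0 CPM (log2 fold change -2.32, SE 0.49, edgeR adjusted p = 0.0022). LOC119659772 was lower, at 214 ± 110.4 against 851 ± 270.4 CPM (log2 fold change -1.99, SE 0.55, edgeR adjusted p = 0.0194). Both had risen in untreated larvae from 2 h to 6 h, by log2 fold changes of 1.48 (edgeR adjusted p = 0.0143) and 2.62 (edgeR adjusted p = 4.9e-04). PBS-injected larvae at 2 h stood at 91.6 ± 42.2 and 97.8 ± 96.5 CPM, so LOC119659772 was not below its 2 h level.

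Over all tested genes, 470 were higher and 291 lower after wounding at 6 h, 278 and 154 of them by at least 2-fold. Of the 432 genes changed at least 2-fold, 33 lay in 7 runs of neighbours. Over 1000 permutations the mean was 0.2 runs (permutation p = 0.000999, the smallest they can give). Without the 3 libraries that stood apart at 6 h (bacteria replicate 4, PBS replicate 3 and untreated replicate 1), 353 were higher and 255 lower. With limma-voom the split turned, to 597 higher and 659 lower. Without the TMM factor it was 557 higher and 114 lower, and that scaling moved the median of all genes to 0.22 on the log2 scale. The total of 761 genes became 138 with only the 10 libraries compared and 285 with the 15 of that time, 338 without PBS replicate 3, 1307 without untreated replicate 1, and 480, 405 and 437 without untreated replicates 2, 3 and 4. LOC119659772 had an edgeR adjusted p of 0.0821 without PBS replicate 3. This was the highest over its edgeR, DESeq2 and limma-voom alternatives, which began at 0.000795.

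With edgeR over all libraries, wounding at 13 h left a short list, nearly all of it higher. LOC119654856 stood at 7.01 ± 8.41 CPM after PBS injection against 2 counts over all untreated libraries, a ratio of 261 with a counting interval of 72.1 to 2151 (edgeR adjusted p = 6.2e-10). Without PBS replicate 3, at 22.0 CPM, the ratio was 121 (33.5 to 1000.6), and without untreated replicates 3 and 4 it was 426 (76.5 to 16825) and 403 (72.4 to 15924). LOC119654694 stood at 114 ± 42.8 against 0.750 ± 0.733 CPM (log2 fold change 7.28, SE 0.48, edgeR adjusted p = 1.1e-14, and 8.02 without untreated replicate 1). Of the 281 genes higher at 2 h, 46 were higher and 0 lower at 13 h, and 22 were higher with only the 10 libraries compared (median log2 fold change 0.22 over the 281 with all libraries, camera p = 1.3e-04 with an estimated correlation). In all, 41 genes were higher after wounding at all 3 times. In the run of 19 genes, 3 were still higher, and the sum was 37.1 ± 28.1 CPM against 19.1 ± 21.0 CPM in untreated larvae. LOC119660572 fell from 400.4 ± 102 to 137 ± 63.4 CPM (log2 fold change -1.55, SE 0.39, edgeR adjusted p = 0.0262). LOC119651047 fell from 255 ± 43.6 to 93.5 ± 39.7 CPM (log2 fold change -1.45, SE 0.35, edgeR adjusted p = 0.0155).

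In total 153 genes were higher and 14 lower at 13 h. Of the 152 genes changed at least 2-fold, 15 lay in 4 runs of neighbours. Over 1000 permutations the mean was 0.026 runs (permutation p = 0.000999, the smallest they can give). There were 0 runs with only the 10 libraries compared or the 15 of that time. With those libraries the total of 167 genes became 39 and 38, and it was 109, 99 and 109 without untreated replicates 1, 3 and 4, and 103 and 92 without PBS replicates 1 and 4. With limma-voom the total was larger and less one-sided, at 411 genes, 304 higher and 107 lower. Over the edgeR, DESeq2 and limma-voom alternatives, LOC119660572 had adjusted p-values from 0.000348 to 0.294 and LOC119651047 from 0.00089 to 0.0926. With the replicate block LOC119660572 was not called (edgeR adjusted p = 0.0577). Neither gene was called with the 10 libraries compared or the 15 of that time. Their log2 fold changes in those fits were -1.55 for LOC119660572 and -1.45 for LOC119651047.

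The wounding effect differed between the 3 times for 410 genes by the edgeR test of the difference. LOC119656618 was among them (edgeR adjusted p = 3.4e-09), with log2 fold changes of 14.15 at 2 h, 4.55 at 6 h (SE 0.71) and 1.66 at 13 h (SE 0.78, not called). LOC119650981 was also among them (edgeR adjusted p = 3.5e-07). Its log2 fold change was -3.26 at 2 h, 0.25 (SE 0.32) at 6 h and 0.31 (SE 0.31) at 13 h, with only the 2 h value called. For LOC119654694 the difference between times was not called (edgeR adjusted p = 0.28), and its log2 fold changes were 6.50 (SE 0.46), 8.02 (SE 0.51) and 7.28 (SE 0.48).

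**Figure D2:**
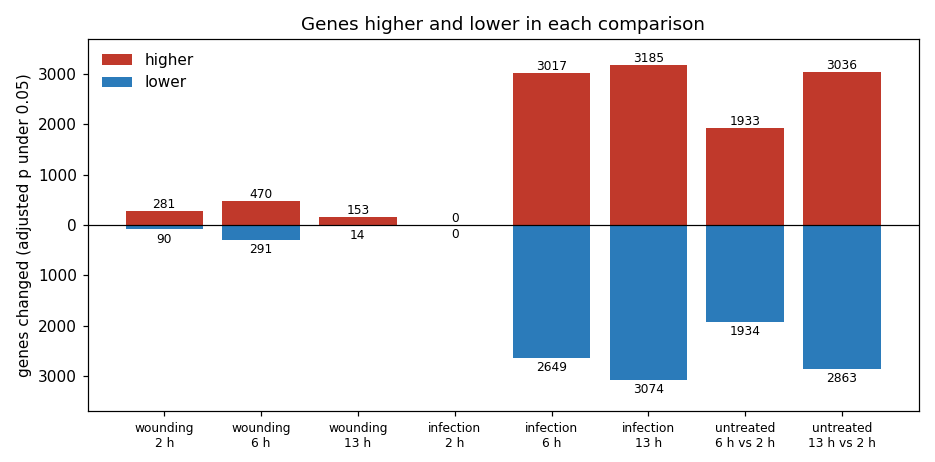
Number of genes called higher (above the line) and lower (below it) in each comparison by edgeR at an adjusted p under 0.05, out of 10485 tested. Infection gave 0 genes at 2 h and 3017 higher and 2649 lower at 6 h, and untreated larvae alone gave 1933 higher and 1934 lower from 2 h to 6 h.

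Infection at 2 h, bacteria-injected against PBS-injected larvae, gave 0 called genes with edgeR. The smallest edgeR adjusted p was 0.73, and 348 genes had an unadjusted p under 0.05, where chance alone gives 524. DESeq2 called 7 genes, 6 higher and 1 lower, and limma-voom called 0. With DESeq2, 6 of the 7 were also called with wounding at 2 h, all in the opposite direction, as the shared PBS libraries alone can give. The run of 19 genes, found in the same PBS libraries, summed to 8542 ± 5246 CPM in bacteria-injected and 6683 ± 2630 CPM in PBS-injected larvae, a difference smaller than the spread between libraries. The median SE of a log2 fold change was 0.25, and simulated changes of 1.5-fold and 2-fold were recovered in 13.4% and 47.8% of cases for this comparison.

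Infection at 6 h changed 54.0% of the tested genes, in both directions. In the run of 19 neighbours that the wound had raised at 2 h, all 19 were higher in bacteria-injected than in PBS-injected larvae, by log2 fold changes of 3.36 to 10.31. Their sum was 14431 ± 3732 CPM against 417 ± 226 CPM. LOC119656629 of that run stood at 127 ± 174 against 0.0415 ± 0.0928 CPM (log2 fold change 10.31, SE 2.22, edgeR adjusted p = 2.5e-04, and 9.43 without bacteria replicate 5). Without PBS replicate 3, which held all 4 of its PBS counts, it was at least 919-fold higher. LOC119656630, also of that run, stood at 432 ± 257 against 1.28 ± 1.42 CPM (log2 fold change 8.40, SE 0.68, edgeR adjusted p = 1.1e-12, and 9.07 without PBS replicate 5). LOC119646979 fell from 27.7 ± 16.1 to 0.0694 ± 0.0774 CPM (log2 fold change -8.56, SE 0.76, edgeR adjusted p = 1.7e-11). Without bacteria replicate 5, which held 3 of its 6 bacteria counts, the ratio of 435 became 707 (counting interval 242 to 3427). LOC119659626 stood at 3.32 ± 4.25 against 862 ± 1044 CPM (log2 fold change -8.0, SE 1.60, edgeR adjusted p = 8.7e-05), or -7.30 without PBS replicate 3 and -9.19 without bacteria replicate 4. The PBS level was itself raised: untreated larvae at 6 h stood at 35.5 ± 77.6 CPM (wounding log2 fold change 4.60, SE 1.37, edgeR adjusted p = 0.0324). At 2 h, PBS-injected and bacteria-injected larvae stood at 0.530 ± 0.379 and 0.338 ± 0.174 CPM. With infection at 13 h it was higher (log2 fold change 7.35, SE 1.78, edgeR adjusted p = 5.6e-04). There it stood at 18.1 ± 31.5 CPM (0.137 to 73.1) against 0.104 ± 0.115 CPM (0 to 0.291) in PBS-injected larvae, so the libraries overlapped.

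Genes selected at 2 h, in libraries not used at 6 h, moved the same way under infection. Of the 281 genes higher after wounding at 2 h, 213 were higher and 7 lower with infection at 6 h (80.9 and 71.0 if independent), with a median log2 fold change of 1.65 (camera p = 1.4e-06 with an estimated correlation). Of the 90 genes lower at 2 h, 71 were lower and 1 higher (22.7 and 25.9 if independent), with a median of -1.71 (camera p = 3.3e-05 with an estimated correlation).

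Among the 12 tested genes of the mitochondrial genome, 6 were lower and 2 higher with infection at 6 h, against 6 lower and 1 higher with DESeq2-type size factors and 4 lower and 4 higher without the TMM factor. CYTB, which encodes cytochrome b of respiratory complex III, fell by 2.36 on the log2 scale (SE 0.51, edgeR adjusted p = 1.9e-04), and by 1.41 without TMM. ND4 of complex I fell by 2.32 (SE 0.41, edgeR adjusted p = 1.2e-05), and by 1.36 without TMM. COX1 of cytochrome c oxidase fell by 1.87 (SE 0.36, edgeR adjusted p = 4.4e-05), and by 0.94 without TMM. COX2 of the same oxidase rose by 0.66 (SE 0.17, edgeR adjusted p = 0.0017), and by 1.46 without TMM. Adjusted over these genes alone, 8 were called, and as a set they were not called with an estimated correlation (camera p = 0.32). In the wounding comparisons and in infection at 2 h and 13 h, 0 of them were called.

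The most abundant gene, LOC119646963, singled out after its values were seen, took 35.0 ± 14.3% of all counts in PBS-injected larvae at 6 h and 39.0 ± 11.6% in untreated larvae at 6 h, but 10.4 ± 1.35% in bacteria-injected larvae at 6 h. What its protein does could not be read from the identifier. Its log2 fold change with infection at 6 h was -2.74 (SE 0.41, edgeR adjusted p = 1.0e-06), and in each of the other 6 groups its mean share lay between 8.33% and 16.3%. It was not among the genes the rule for named genes took. In PBS replicate 3 at 6 h its share was 10.4%, and in untreated replicate 1 at 6 h it was 19.5%.

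**Figure D3:**
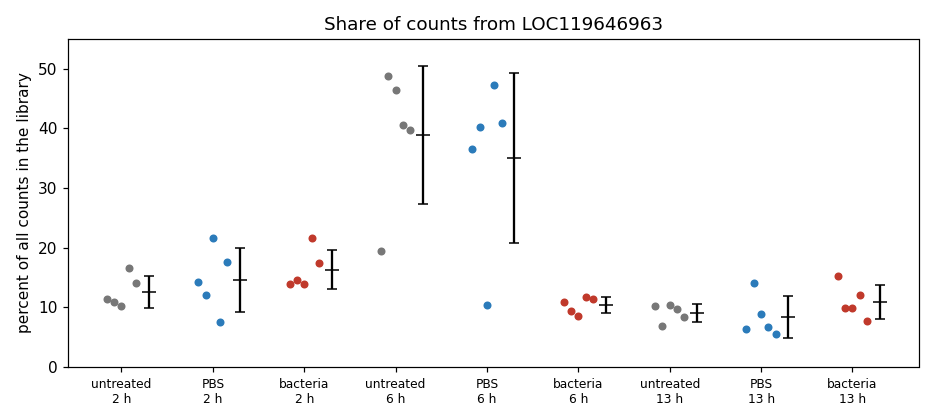
Percent of all counts in a library that came from LOC119646963, with 1 point per library and the mean ± SD (n = 5) beside each group. Untreated and PBS-injected larvae at 6 h averaged 39.0% and 35.0%, and bacteria-injected larvae at 6 h 10.4%.

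In all, 3017 genes were higher and 2649 lower with infection at 6 h, 1752 and 1501 of them by at least 2-fold. Without the 3 libraries that stood apart at 6 h, 2839 were higher and 2654 lower. Of the 3253 genes changed at least 2-fold, 448 lay in 116 runs of neighbours. Over 1000 permutations the mean was 67.3 runs (permutation p = 0.000999, the smallest they can give). In bacteria replicate 4, which stood apart from its group, LOC119656630 and LOC119659626 were at 875 and 10.8 CPM. Without the TMM factor the split was 5991 higher and 812 lower and the runs were 471, since that scaling put the median of all genes at 0.87 on the log2 scale in place of 0.09. LOC119656629 was not called by limma-voom, with an adjusted p of 0.352 in a range from 3.4e-07 over its alternatives.

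Infection at 13 h changed a similar number of genes, 3185 higher and 3074 lower. LOC119658402 stood at 31.3 ± 20.7 CPM in bacteria-injected larvae with 0 counts in PBS-injected larvae, at least 911-fold higher (edgeR adjusted p = 1.8e-11). LOC119656627, of the run of 19, stood at 61.9 ± 76.3 against 0.0584 ± 0.0883 CPM (log2 fold change 9.88, SE 1.02, edgeR adjusted p = 1.3e-10). Its ratio of 1080 became 488 without bacteria replicate 5 and 2234 (counting interval 618 to 18444) without PBS replicate 2. LOC119651106 stood at 56.3 ± 45.2 CPM in PBS-injected larvae against 3 counts over all bacteria libraries, a ratio of 1435 with a counting interval of 491 to 6958 (edgeR adjusted p = 8.3e-12), or 3376 (606 to 133361) without bacteria replicate 4. LOC119654859 was at 6.49 ± 7.37 CPM in PBS-injected larvae with 0 counts in bacteria-injected larvae, at least 165-fold lower (edgeR adjusted p = 3.2e-08), or at least 89.8-fold lower without PBS replicate 4. The PBS level of LOC119654859 was itself raised: untreated larvae at 13 h stood at 0.698 ± 0.824 CPM (wounding log2 fold change 3.21, SE 0.71, edgeR adjusted p = 0.0081). All 19 genes of the run were higher, and their sum was 3402 ± 1448 CPM against 37.1 ± 28.1 CPM.

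Of the 281 genes higher after wounding at 2 h, 216 were higher and 22 lower with infection at 13 h (85.4 and 82.4 if independent), with a median log2 fold change of 1.99 (camera p = 2.4e-05 with an estimated correlation). Of the 90 genes lower at 2 h, 68 were lower and 4 higher (median -1.99, camera p = 2.8e-04 with an estimated correlation). Of the 3898 genes changed at least 2-fold, 878 lay in 219 runs of neighbours. Over 1000 permutations the mean was 114 runs (permutation p = 0.000999, the smallest they can give). Of the genes tested, 1501 were higher and 1167 lower with infection at both 6 h and 13 h (916 and 777 if independent). In opposite directions 851 were called, which is fewer than independent lists would give. The excess of higher genes at 13 h turned without a filter, to 2914 higher and 3495 lower. Without the TMM factor the split at 13 h was 3232 higher and 2263 lower, with the median of all genes at 0.12 on the log2 scale.

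**Figure D4:**
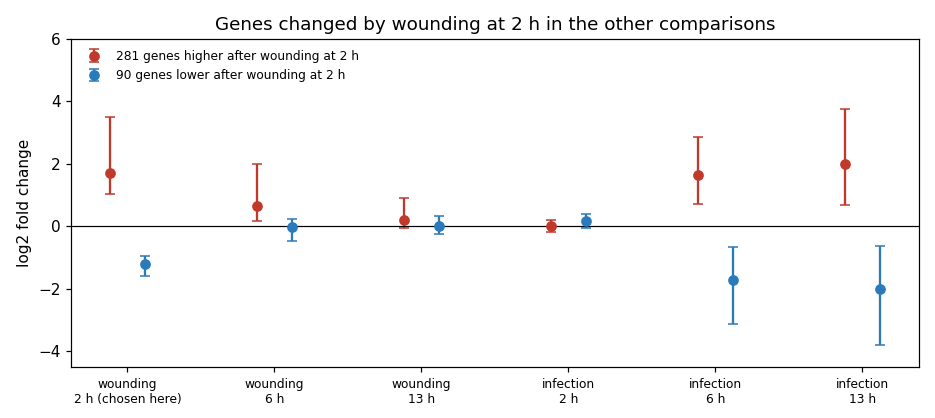
Median log2 fold change, with bars from the lower to the upper quartile over genes, of the 281 genes higher and the 90 genes lower after wounding at 2 h, in each wounding and infection comparison. The genes were chosen in the leftmost comparison, and their medians with infection were 0.01 and 0.18 at 2 h, 1.65 and -1.71 at 6 h, and 1.99 and -1.99 at 13 h, where infection at 2 h shares the PBS libraries the genes were chosen on, so that medians on the other side of 0 are expected there without a change.

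The infection effect differed between times for 6825 genes (edgeR test of the difference). LOC119656630 was among them (edgeR adjusted p = 2.9e-11), as was LOC119646979 (edgeR adjusted p = 3.0e-08). LOC119646979 had a log2 fold change of -0.21 (SE 0.61) at 2 h, -8.56 at 6 h and -1.84 (SE 1.23) at 13 h, with only the 6 h value called. Its level in PBS-injected larvae was 27.7 CPM at 6 h, but 0.891 ± 0.398 CPM at 2 h and 0.169 ± 0.217 CPM at 13 h. There was thus little for infection to lower at 2 h and 13 h. LOC119646963 was also among the genes whose infection effect differed (edgeR adjusted p = 1.7e-05), with 0.12 (SE 0.38) at 2 h and 0.23 (SE 0.38) at 13 h.

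The overlap of the wounding and infection responses at one time is read against the PBS-injected libraries they share with opposite sign. At 6 h, 439 genes were called in both. Of these, 170 were higher in both, 152 lower in both, 94 higher with wounding and lower with infection, and 23 the reverse, where independent lists give 135, 73.5, 119 and 83.7. Simulated unchanged groups sharing the PBS libraries gave a mean of 0 genes in both. With no gene changed this was fixed in advance, so it is no measure for the 439. Their covariance was -0.11, against 0.20 observed, a difference of 0.31 (across genes, which are not independent replicates, r was 0.16 observed and -0.53 simulated). The simulation drew genes independently and was fitted on the 15 libraries of a time. With the PBS libraries split 2 and 3 between the comparisons, the median over 20 splits was 236 genes in both (69 to 598), with a median of 187.5 of the same sign, and a covariance of 0.32 (0.0196 to 0.788). Without the TMM factor 310 genes had the same and 60 the opposite sign at 6 h, against 322 and 117. At 13 h, 125 genes were called in both: 39 higher in both, 3 lower in both, 78 higher with wounding and lower with infection, and 5 the reverse (46.5, 4.10, 44.9 and 4.25 if independent). This balance, 42 with the same and 83 with the opposite sign, became 14 and 14 with only the 10 libraries compared and turned to 16 and 10 with the 15 of that time. The covariance was -0.17 against -0.09 simulated, and the split PBS libraries gave a median of 78.5 genes (25 to 247) and a covariance of -0.09 (-0.246 to 0.0367, on both sides of 0). At 2 h the overlap was 0 genes, since edgeR called 0 genes with infection there (348 at an unadjusted p under 0.05). It was 6 genes with DESeq2, 0 with the same and 6 with the opposite sign, as the shared PBS libraries alone can give. The overlap at 6 h was 861 without untreated replicate 1, 281, 243 and 262 without untreated replicates 2, 3 and 4, and 211 without PBS replicate 3. That at 13 h was 73 without untreated replicate 3, and 74 and 70 without PBS replicates 1 and 4.

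Untreated larvae changed widely with time alone. LOC119646963 rose from 2 h to 6 h by a log2 fold change of 2.55 (SE 0.41, edgeR adjusted p = 2.5e-05), and of the 12 mitochondrially encoded genes 5 rose and 1 fell, against 3 and 5 without TMM. CYTB rose by 2.74 (SE 0.51, edgeR adjusted p = 1.3e-04), and by 1.78 without TMM. COX2 fell by 0.59 (SE 0.17, edgeR adjusted p = 0.0082), and by 1.26 without TMM. COX3 was higher by 0.64 and stood at -0.16 without TMM, where it was not called. As a set, the mitochondrially encoded genes were not called with an estimated correlation (camera p = 0.30). From 2 h to 6 h, 1933 genes were higher and 1934 lower, and from 2 h to 13 h, 3036 were higher and 2863 lower. Without the TMM factor the split from 2 h to 6 h was 421 higher and 6017 lower, with the median of all genes at -0.85 on the log2 scale, and that from 2 h to 13 h was 2155 higher and 3089 lower.

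The untreated change from 2 h to 6 h ran against the infection effect at 6 h, with which it shares no library. Of the 5666 genes called with infection at 6 h, 2451 had changed in the opposite direction and 166 in the same direction from 2 h to 6 h in untreated larvae, where independence gives 1045 for each. Across genes, which are not independent replicates, r was -0.46 and Spearman's rho -0.56. With the untreated change from 2 h to 13 h, the infection effect at 6 h went the same way (r 0.32), for 2804 genes in the same and 610 in the opposite direction, where independence gives 1597 and 1591. A position was computed for each library from the 3867 genes called in untreated larvae, with 0 at the untreated 2 h mean and 1 at the untreated 6 h mean. PBS-injected larvae at 6 h stood at 0.822 ± 0.196 and bacteria-injected larvae at 6 h at 0.0277 ± 0.128, a difference larger than the spread between libraries (exact permutation test, two-sided, p = 0.00794, the smallest that 5 against 5 libraries can give). At 13 h the 3 groups stood between -0.0586 and 0.0948.

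**Figure D5:**
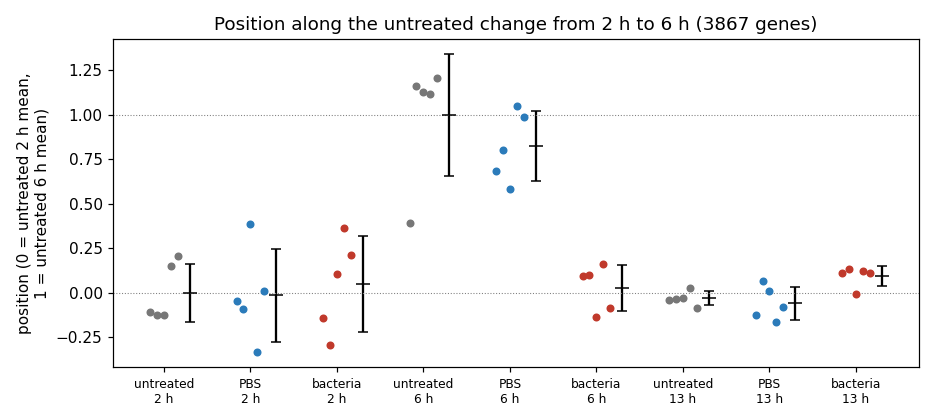
Position of each library (1 point each) along the change of untreated larvae from 2 h (0) to 6 h (1), with the mean ± SD (n = 5) beside each group. PBS-injected larvae at 6 h averaged 0.822 and bacteria-injected larvae at 6 h 0.0277, and untreated replicate 1 at 6 h stood at 0.390, below the rest of its group.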

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

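Of the tests in this part, those of the position on the untreated axis, of the shift by the most abundant gene, of the calls left by TMM, of bacteria replicate 4 at 6 h and of the 2 h infection result were chosen after the result was seen, plain library-size scaling was chosen after seeing the data but its bounds before its result, and the thinning and regrouping tests were set out before.

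Infection at 6 h called 5666 genes, and thinning its 10 libraries to 7.45 M counts each left 5551 genes, 5430 of them shared, which argues against a difference in depth, and leaving LOC119646963 out under plain library-size scaling, which moved the median of all genes from 0.87 to 0.43, left 6029 genes, 4304 higher and 1725 lower, which argues against a shift by that gene alone. Under that scaling with LOC119646963 kept, 406 genes were lower by at least 2-fold, between the bounds for and against a few abundant genes, but TMM moved the median from 0.87 to 0.09 and left 3017 higher and 2649 lower, which argues against a shift by a few abundant genes as the whole cause. The bacteria 6 h libraries stood at 0.0277 on the untreated axis from 2 h to 6 h, all 5 below every PBS library, so a candidate explanation is that infected larvae lacked a change that other larvae went through, but the infection effect also went with the untreated change from 2 h to 13 h (r 0.32). Over 167 genes high at 13 h and low before in untreated larvae, bacteria replicates 1, 2, 3 and 5 at 6 h stood at median fractions of 0.00077 to 0.00228 of the bacteria 13 h mean, which argues against a 13 h state in them, while a smaller advance in time stays open. The labels give no batches, so a batch effect was not tested.

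Bacteria replicate 4 at 6 h had a first principal component of 38.3, against -43.6 to -38.4 in its group. Over 167 genes high at 13 h and low before in untreated larvae, it stood at a median fraction of 0.0696 of the bacteria 13 h mean, while each bacteria 13 h library stood at 0.635 or more, which argues against a 13 h library under a wrong label. Over 236 genes chosen in the bacteria libraries instead, the median was 0.208. Over the 167 genes the log2 fractions had an interquartile range of 4.19, against 1.90 at most in the bacteria 13 h libraries. Over the 236 genes these were 3.88 and 1.85, but those genes were chosen as high in every bacteria 13 h library, which partly fixes the second value. The other bacteria 6 h libraries had ranges of 3.09 to 3.96 over the 167 genes. For replicate 4 the range over the 167 genes argues against admixture of 13 h RNA in 1 common proportion. That the larvae of replicate 4 were ahead of their group in time remains open and was not tested.

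Infection at 2 h called 0 genes with edgeR, with 348 at an unadjusted p under 0.05 and 7 by DESeq2. Wounding at that time, with as many libraries, called 371 genes, which argues against too few libraries for changes of that size, while smaller changes stay open. Over the 3253 genes called at 6 h with at least a 2-fold change, the 2 h and 6 h infection effects had an r of -0.0236 across genes, which are not independent replicates (jackknife SE over libraries 0.387), and 0.128 (SE 0.227) with the untreated change from 2 h to 6 h held constant. Whether an early form of the 6 h response lay below the threshold therefore stays open.

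Values of single libraries far from the rest of their group are given next, 15 among 112 groups of 5 examined. Chance gives 5.6 for independent and normally distributed values. Several measures here share the same libraries and some CPM values lie near 0, so no excess over chance is read from this. PBS replicate 3 at 6 h had 17.2 M counts against 7.45 to 8.56 M. The mitochondrially encoded share was 2.85% in untreated replicate 2 at 13 h and 5.73% in bacteria replicate 2 at 2 h, whose second principal component was 35.7 against 14.3 to 19.0. Bacteria replicate 1 at 13 h had 11160 genes detected against 11599 to 11707. The run of 19 genes summed to 55.7 CPM in untreated replicate 4 at 13 h. On the untreated axis, untreated replicate 1 at 6 h stood at 0.390 against 1.12 to 1.20, and bacteria replicate 3 at 13 h at -0.00499. LOC119654856 was at 22.0 CPM in PBS replicate 3 at 13 h, LOC119654694 at 2.03 CPM in untreated replicate 1 at 13 h, and LOC119656629 at 0.207 CPM in PBS replicate 3 at 6 h with 0 in the others. LOC119656630 was at 875 CPM and LOC119659626 at 10.8 CPM in bacteria replicate 4 at 6 h, and LOC119656627 at 197 CPM in bacteria replicate 5 at 13 h.

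By the edgeR test of the difference between times, the wounding effect differed for 410 genes and the infection effect for 6825. The 9 rows that named no gene, left out of the counts of genes, were tested in a separate fit with p-values adjusted over the 9 alone: 3 changed with wounding at 6 h, 6 with infection at 6 h and 8 with infection at 13 h.

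Other splits of the same libraries, 100 for each comparison with the real one included, were fitted on the libraries compared. For wounding, the real labels gave 329, 138 and 39 genes at 2, 6 and 13 h and the highest other split 2, 40 and 4. Each time 1 of 100 splits, the real one, reached the count, which argues against chance but cannot exclude it. For infection the real labels gave 4591 and 6447 genes at 6 and 13 h, against 1 and 34 at most, which also argues against chance. At 2 h all 100 splits reached the real count of 0, and the highest gave 1487, which points to a structure among those libraries. For untreated larvae from 2 h to 13 h the real labels gave 6369 and the others 0. From 2 h to 6 h they gave 3596, and 2 of 100 splits reached it. The other, with 4484 genes, exchanged untreated replicate 1 at 6 h with untreated replicate 5 at 2 h. The real labels were therefore not the split that called the most genes, and chance is made unlikely but not excluded. For the tests of differences between times, with treatments permuted within times, the real values were 395 for wounding and 6444 for infection. The highest permuted values were 141 and 3678, which argues against chance without excluding it.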

How the results depend on the processing

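Each gene named by the rule, and LOC119646963, kept its direction under each alternative run for it. The rule took only called genes without overlap between the groups, so for them this was nearly fixed in advance and says little about the processing. The balance of calls turned in some: wounding at 6 h from 470 higher and 291 lower to 597 and 659 with limma-voom, infection at 13 h from 3185 and 3074 to 3110 and 3167 with DESeq2-type size factors, 2914 and 3495 without a filter, 3382 and 3415 with the 15 libraries of the time, 3043 and 3099 without bacteria replicate 3 and 2991 and 3025 without bacteria replicate 5. The untreated change from 2 h to 13 h turned from 3036 and 2863 to 2155 and 3089 without TMM, and that from 2 h to 6 h, 1933 and 1934, fell on either side. The overlap at 13 h went from 42 with the same and 83 with the opposite sign to 14 and 14 with the 10 libraries compared and 16 and 10 with the 15. In addition, 2 mitochondrially encoded genes called in the main fit changed sign without TMM and were then not called: ND1 with infection at 6 h, from -0.83 to 0.050, and COX3 in untreated larvae from 2 h to 6 h, from 0.64 to -0.16. The alternatives without 3 libraries at 6 h, without TMM and without the most abundant gene were chosen after seeing the data. The replicate numbers did not pair the libraries: over 30 same-numbered pairs the correlation of deviations across genes was -0.52 to 0.31, 10 were above 0.1, and 4 correlated best with their own number. With the replicate block, wounding at 2, 6 and 13 h gave 358, 684 and 146 genes, and infection 0, 5585 and 6209. Fewer genes pass stricter thresholds by construction, and fewer libraries give a spread estimated from less data. The cause of the other changes was not tested.

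Gene counts that moved by over 1.5 times were these. With limma-voom, wounding gave 1256 genes at 6 h and 411 at 13 h, its difference between times 1080, the untreated change from 2 h to 6 h 6546, and the overlap 848 at 6 h and 322 at 13 h. With DESeq2, infection at 2 h gave 7 genes and the overlap at 2 h 6. With only the 10 libraries compared, wounding gave 138 and 39 genes at 6 and 13 h and the overlap 89 and 28. With the 15 libraries of the time these were 285, 38, 187 and 26. At an adjusted p under 0.01, wounding gave 273 and 86, the overlap 137 and 61, the difference of wounding between times 176, and the untreated change from 2 h to 6 h 2313. With a log2 fold change of at least 1, wounding at 6 h gave 432, infection 3253 and 3898 at 6 and 13 h, the overlap at 6 h 195, and the untreated change 1662 to 6 h and 3600 to 13 h. Without TMM the untreated change to 6 h was 6438. With the PBS libraries split, the overlap was 236 and 78.5. Of the genes higher after wounding at 2 h, 63 and 22 were also higher at 6 and 13 h with only the 10 libraries compared, and 22 at 13 h with the 15 of the time. Runs of neighbours became 13 with limma-voom for wounding at 2 h, 2 with the replicate block and 0 with the 10 or 15 libraries for wounding at 13 h, and 75 without a filter and 471 without TMM for infection at 6 h. Mitochondrially encoded genes called with infection at 6 h became 5 with a log2 fold change of at least 1. The correlation of the untreated change to 6 h with the infection effect at 6 h moved from -0.46 to between -0.59 with limma-voom and -0.35 without a filter.

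With 1 library left out, wounding gave 313 to 403 genes at 2 h, 338 to 1307 at 6 h and 92 to 212 at 13 h. Infection gave 0 at 2 h each time, 5168 to 5725 at 6 h and 5889 to 6221 at 13 h. The overlap was 211 to 861 at 6 h and 70 to 157 at 13 h, and the differences between times 297 to 597 for wounding and 6442 to 7263 for infection. Of the values of named genes, 9 of 210 with a library left out and 7 of 228 under other alternatives fell under the threshold. The 15-library fit cannot be made for the untreated change, which spans times, the fits on fewer libraries were not run for the differences between times, and no alternative was run for the gene lists, which had 0 members. At 2-fold, the simulated data gave a recovery of 35.8% to 58.2%, and at 1.5-fold one of 7.46% to 13.4%, so many changes of that size can be missed.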

Other observations

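The tests in this part were chosen after the result was seen.

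Long noncoding RNAs were called less often than protein-coding genes with infection at 6 h and 13 h and in untreated larvae from 2 h to 13 h. With infection at 6 h, 79 of 206 were called (26 higher and 53 lower, 38.3%), against 54.4% of 10269 protein-coding genes (Fisher's exact test, two-sided, adjusted p = 1.9e-05 over 7 comparisons). With infection at 13 h, 93 were called (52 higher and 41 lower, 45.1%), against 6162 protein-coding genes (adjusted p = 4.9e-05). In untreated larvae from 2 h to 13 h, 72 were called (35 higher and 37 lower), against 5827 protein-coding genes (adjusted p = 4.2e-09). From 2 h to 6 h, 74 were called, 66 of them higher, and the share did not differ from that of protein-coding genes beyond chance (adjusted p = 0.83). The levels of these classes were not compared.

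Libraries of the same group at 2 h differed along genes that changed between 2 h and 6 h without treatment. Over the PBS-injected and bacteria-injected libraries at 2 h, taken as deviations from their group means, the first component held 39.1% of the variance. Across the 10485 genes, its weights correlated with the untreated change from 2 h to 6 h at an r of 0.554 in size, in libraries the untreated change does not use, against 0.163 for the untreated change from 2 h to 13 h and 0.103 for the wounding effect at 2 h. On the axis of the untreated change, PBS libraries at 2 h ranged from -0.333 to 0.386 and bacteria libraries from -0.294 to 0.366. A hypothesis is that pools of larvae collected together may stand at different points of 1 temporal programme. Whether that programme follows the hour of day, feeding or growth was not tested.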
